A study of Drosophila melanogaster with 48 samples.

How the data were processed

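The series comprises 48 ATAC-seq libraries of S2 cells, in groups of 2, and the files used here are 10 narrowPeak lists in dm6 coordinates. Per the submitters' processing notes, the tools named are Bowtie2, MACS2, featureCounts, DESeq2 and deepTools 3.5.1; their settings and the role of each are not given in the sources used here. How reads were shifted for the transposase is likewise not given. Per the labels, each main list covers control and factor libraries together and each full-length titration list covers all doses. In the deposited lists, the authors give each peak a fold enrichment (a ratio over background), a −log10 p, a −log10 q, a score and a summit; the smallest −log10 q is 1.30 in every list. The 2 DBD titration lists hold windows of 200 bp with no summit, for which the midpoint was used. After rows of 1 region were joined, their regions had a median width of 200 bp. The widest was 1609 bp in the Grh DBD titration list and 1957 bp in that of the Zld DBD. Depth per sample is unknown, and the precision of shares is given by exact binomial intervals over regions.

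Rows with several summits of 1 region were joined to 1 region with the strongest summit. All rows lie on the 7 chromosomes 2L, 2R, 3L, 3R, 4, X and Y. Regions were called shared with an overlap of at least 1 bp. An only-region of a factor is a main-list region that overlaps the factor's titration list and none of the 4 lists of the other 2 full-length factors. Main and titration lists come from separate libraries. Genes come from the RefSeq table of Release 6 (17807 genes, of which 13946 are protein-coding), which gives start and end but was used without strand or exons. Each region was assigned to the protein-coding gene with the nearest end. Of 174 symbols in the 8 gene lists, 4 were matched by synonym and 1 was not matched.

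Before the data were examined, the definitions, tests, gene lists and main alternatives were fixed. Gene lists were tested against 10000 random lists of the same size matched on territory length in 20 bins (permutation test, two-sided, smallest p 0.0002), with Benjamini-Hochberg adjustment over 24 tests. Shares were compared with two-sided Fisher's exact tests or, for the same regions in different lists, exact McNemar tests, adjusted over the factors compared. The threshold was an adjusted p of 0.05. Genes were named by a rule: the nearest gene of the 10 only-regions with the highest fold enrichment, the genes of the factor's fixed list, and grh, zld, twi and MtnA. Genes named outside it are marked as chosen after their values were seen.

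Parts of the plan changed. Motif shares, the k-mer scan and the test of motif against peak strength were not run, since no genome sequence was used here. Distance to a transcription start site was replaced by distance to the nearer gene end, and the check for introduced sequence used gene bodies instead of coding exons. Alternatives were a −log10 q of at least 10, the same number of regions per list (25397, by −log10 q), overlap of at least 50% of the shorter region, main lists or titration lists alone, distances of 1000 and 200 bp, assignment within 10 kb, an unmatched exact test and the DBD titration lists. Added after the data were seen were the comparison of main-list regions with the titration lists, matching on the number of regions, lists without the factor's own gene, DBD lists counted as other lists, X shares and gene families.

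The gene list test was tested on simulated data of 200 draws per set, with 28 random genes per list among 13946 genes. With region numbers as for Grh, Zld and Twi, it called 0.5%, 1.5% and 0.5% of lists with no effect. It called 100.0% of lists in which 8 genes were given a region. Simulated regions lay at uniform positions and 8 of 28 genes is a large effect, so this rate does not show how often a smaller one would be called. These calls used the p before adjustment, so the rates do not carry over to the adjusted tests of the real lists. For example, mesoderm genes with Zld-only regions had a p of 0.0114 before adjustment and 0.137 after it (permutation test). The overlap function gave no difference from direct comparison over 2000 regions. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.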

Results

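Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts and tags open DNA, in Drosophila S2 cells, a cultured line with the character of hemocytes (insect blood cells). The cells carried a copper-inducible full-length Grainyhead (Grh), Zelda (Zld) or Twist (Twi), or the DNA-binding domain (DBD) of Grh or Zld alone. Grh is a regulator of epidermal genes, Zld activates the early zygotic genome and Twi directs mesoderm formation. The series holds 48 libraries, taken 48 h after CuSO4 was added, with 2 libraries per group. Wild-type S2 cells received the same dose in the main experiments, which used 100 uM for Grh, 1000 uM for Zld, 40 uM for Twi, 20 uM for the Grh DBD and 100 uM for the Zld DBD. Titrations used 0, 25, 100 and 400 uM for Grh, 0, 500, 1000 and 1500 uM for Zld and 0, 10, 40 and 160 uM for HA-tagged Twi. The DBD titration libraries received 80 uM for the Grh DBD and 400 uM for the Zld DBD. The design asks which regions are open when each factor is present and whether a DBD alone is enough.

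The values analysed here are 10 peak lists. Each main list was called by the authors over control and factor libraries together, and each full-length titration list over all doses. No list belongs to 1 library, so no value per replicate, no depth per sample and no comparison between doses can be given, and the depth is unknown. Shares carry exact binomial 95% intervals that cover counting error over regions only. Regions are not replicates, and each p-value describes these lists and not the spread between cultures.

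The lists held between 25397 regions (HA-Twi titration) and 71754 regions (Twi). The Grh list held 44658 regions and its titration list 30394, and the Zld list held 33943 and its titration list 27064. The DBD lists held 29997 regions for Grh and 34647 for Zld, and the DBD titration lists 28164 and 29048. The long lists carried many weak regions, since 32331 Twi regions and 19816 Grh regions had a deposited −log10 q of at least 10, against 23162 for Zld. Regions found in all 6 full-length lists made up 45.6% of the Grh list (20344 regions), 58.9% of the Zld list (19998) and 27.6% of the Twi list (19817). Of the fixed gene lists, hemocyte genes were nearest to a region of all 6 lists for 18 of 22 genes, against a mean of 11.8 in random lists, and the permutation test gave an adjusted p of 0.0928 over 8 lists. No list passed in that test. Germline genes stood at 10 of 11, Polycomb and Hox genes at 14 of 18, copper response genes at 11 of 16, epidermal barrier genes at 19 of 28, early zygotic genes at 20 of 34, neuronal genes at 7 of 12 and mesoderm genes at 15 of 32, against 58.9% of all 13946 protein-coding genes.

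Regions over the genes of the expressed factors differed between the lists. A region of 4764 bp at X:19777526-19782289 (dm6) lay inside zld in the Zld list, with a fold enrichment of 3.40. The widest region inside zld in the Zld titration list was 3058 bp, and the Zld DBD lists held regions of 1125 bp (fold enrichment 10.2) and 1183 bp (10.7). The widest region over zld in any list of another factor was 271 bp. Over twi, the widest region was 1223 bp in the Twi list and 1213 bp in the HA-Twi titration list, against at most 606 bp in lists of other factors, and a region at 2R:23047827-23048079 was present in both Twi lists only, with fold enrichments of 6.22 and 6.24. Inside grh, the widest region was 1253 bp in the Grh list and 1231 bp in its titration list, against at most 655 bp elsewhere. Regions over grh that were absent from the lists of other factors reached a fold enrichment of 17.6 in the Grh DBD titration list. The gene table used has no exons, so it was not determined which of these regions cover coding sequence. MtnA, a copper-inducible metallothionein, held a strong region in all 10 lists, with a highest fold enrichment between 18.6 and 39.2. No replicate value exists for these counts, and fold enrichments are the authors' own and were not compared across lists by a test.

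**Figure D1:**
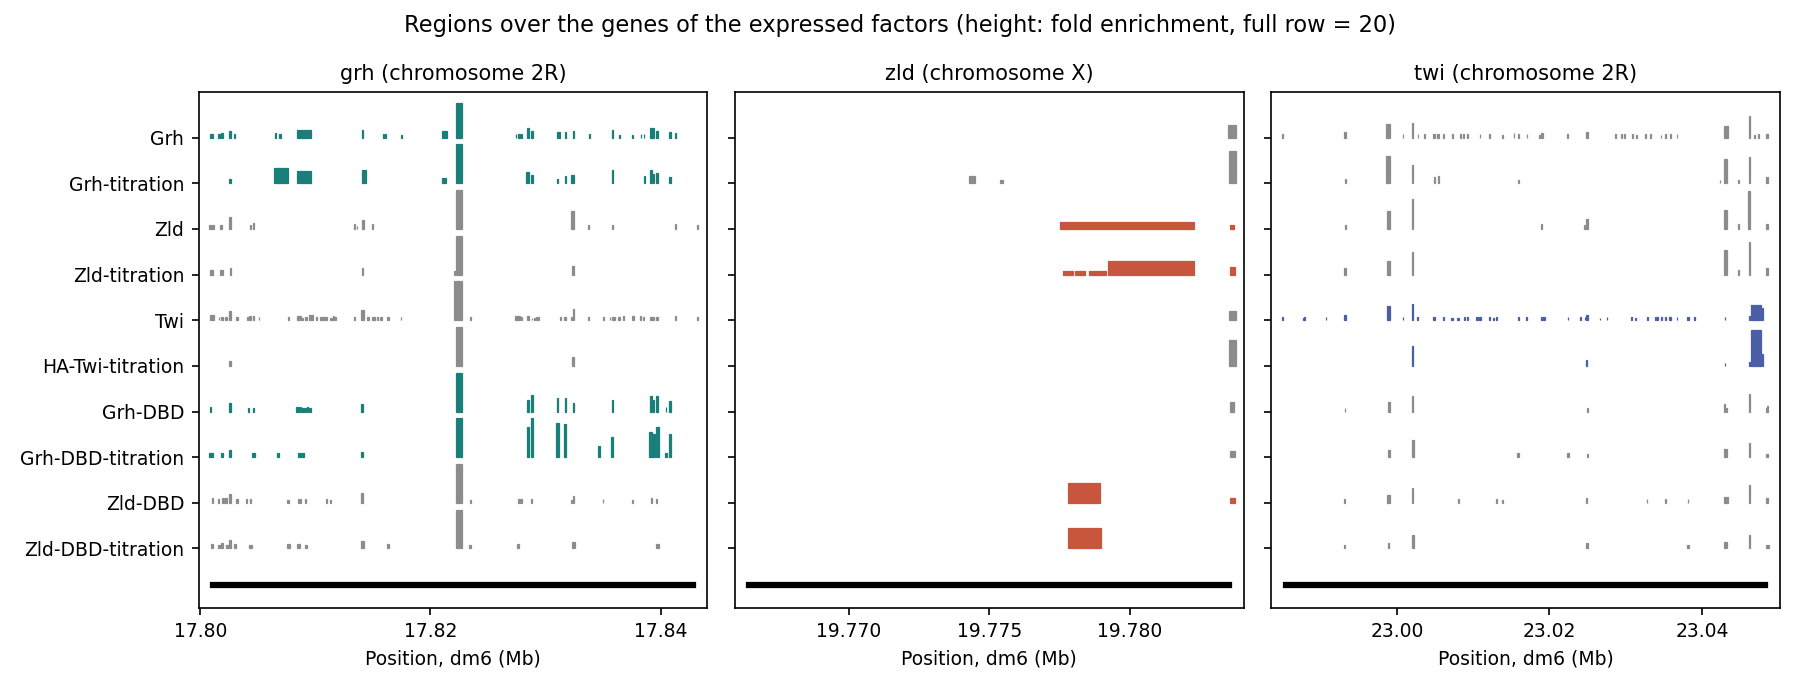
Regions of each of the 10 lists (rows) over grh, zld and twi (panels) by dm6 position in Mb, with the gene as a black line below. Height is the authors' fold enrichment within a list, drawn up to 20, and coloured regions belong to lists of the factor itself; the 4764 bp region inside zld is in the Zld list.

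A total of 813 Grh regions were also in the Grh titration list and in none of the 4 lists of the other factors. They are called Grh-only regions. The Grh list pools wild-type and Grh libraries, and the Grh titration list includes cells given no copper. The lists of Zld and Twi are built alike. An only-region may therefore also be open in cells without the factor. Opening that depends on the factor was not tested for the only-regions of any factor. Grh-only regions lay nearest to 679 genes and had a median fold enrichment of 1.92, against 4.40 for Grh regions found in all 6 lists. The strongest lay inside dac, which encodes a transcription factor of eye and leg development, at 2L:16477602-16477868 with a fold enrichment of 7.48. Next came regions inside CG43759 (X:18938378-18938494, 6.00), inside EcR, the ecdysone receptor (2R:6158031-6158267, 5.23), inside CG6040 (3R:19111262-19111546, 5.18) and inside pcs, nearest to an end of CG7639 (2R:14986776-14986943, 4.85). The other 5 of the 10 strongest were nearest to corto (fold enrichment 4.82), CG8379 (4.77, inside pyd, a cell junction gene), CG30159 (4.65, inside Tsp42Ea), CG6749 (4.52) and CG32170 (4.35, inside Lmpt).

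Grh-only regions lay nearest to 10 of the 28 genes of the epidermal barrier list, against a mean of 2.29 in random lists matched on gene territory. None of 10000 random lists held as many, and the permutation test gave an adjusted p of 0.0048 over the 24 tests, from the smallest p that these lists can give. The genes were grh itself, the septate junction genes Fas3, cora and Lac, the E-cadherin gene shg, the chitin synthase gene kkv, the chitin deacetylase genes serp and verm, and the developmental regulators Ubx and dpp. Their strongest regions had fold enrichments of 3.41 for grh, 2.88 for Fas3 (2L:18327254-18327386, inside the gene), 2.76 for shg (2R:21047832-21048044, outside genes), 2.34 for serp and 2.31 for cora. Lac stood at 2.22, dpp at 2.14, kkv at 1.93, Ubx at 1.89 and verm at 1.81. With main lists alone the count was 13 genes against a mean of 8.57 and was no longer called by the permutation test (adjusted p = 0.545). By regions, 17 of 813 Grh-only regions (2.09%, 1.22 to 3.33) and 2 of 663 only-regions of Zld and Twi (0.302%, 0.0366 to 1.09) lay nearest to these genes, which differed by Fisher's exact test (adjusted p = 0.00588) but not once grh was left out (12 of 808 regions, exact adjusted p = 0.0831).

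A total of 367 Zld-only regions lay nearest to 316 genes, with a median fold enrichment of 2.20. The strongest lay nearest to CG15059 (X:18263824-18264422, 4.92), to the zinc transporter gene ZnT35C (2L:15247641-15247886, 4.80, 79 bp from a gene end), to CG31262 (3R:17213695-17213867, 4.56) and to the cell polarity gene baz (X:17162249-17162575, 4.45, inside the gene). The others of the 10 strongest were nearest to CG5171 (fold enrichment 4.39), the tubulin gene betaTub97EF (4.37), the Toll family receptor gene Tollo (4.33), Cyp4ac1 (4.16, inside tkv), fend (4.14) and CG11726 (4.07). Of 34 early zygotic genes, only sna, a transcription factor of the mesoderm, was nearest to Zld-only regions, which stood 11122 and 11469 bp from a gene end, at 2L:15465423-15465575 (2.79) and 2L:15465069-15465213 (2.61). The mean of random lists was 1.76 genes and the permutation test gave an adjusted p of 1.0. By regions, 2 of 367 Zld-only regions (0.545%) and 3 of 1109 other only-regions (0.271%) lay nearest to early zygotic genes, with an adjusted p of 0.603 in Fisher's exact test. All libraries at 500 uM copper and above belong to the Zld lists, so Zld and high copper cannot be separated in this set.

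The 296 Twi-only regions made up 1.03% of the 28642 Twi regions absent from the lists of the other factors. The same share was 18.8% for Grh and 20.2% for Zld. Twi regions absent from the other main lists were found less often in the HA-Twi titration list (1.91%) than in that of Grh (3.19%). The Twi-only regions lay nearest to 264 genes, with a median fold enrichment of 1.95. The strongest lay nearest to the serotonin transporter gene SerT (2R:24411066-24411511, 6.81), followed by regions inside raskol (X:17728856-17729090, 6.39), twi (2R:23047827-23048079, 6.22) and bol, a germline RNA-binding protein gene (3L:9113646-9113924, 6.04). The other 6 were nearest to CG32369 (fold enrichment 5.69), CG6527 (5.22, inside Rbfox1), side-IV (4.98), the tyrosine kinase gene Btk (4.78), CG43658 (4.66) and Cph (4.64). Of 32 mesoderm genes, 5 were nearest to Twi-only regions: twi, the FGF receptor gene htl (2.84), the RNA-binding protein gene how (2.76), the gastrulation gene fog (1.81) and the integrin gene if (1.53). The mean of random lists was 1.5 genes and the permutation test gave an adjusted p of 0.203. The twi region lies inside the gene of the expressed factor, where reads from introduced sequence were not excluded. Without twi, 4 of 31 genes remained against a mean of 1.49 (permutation test, adjusted p = 0.822). With all 32 genes, an unmatched Fisher's exact test called the mesoderm list with Twi-only regions (adjusted p = 0.00248). It also called the list with Zld-only regions (adjusted p = 0.000854). By regions, 5 of 296 Twi-only regions (1.69%) and 11 of 1180 others (0.932%) lay nearest to mesoderm genes, with an exact adjusted p of 0.512.

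With the main definitions, no other pair of a gene list and a set passed the permutation test. The lowest adjusted p among them was 0.137, for mesoderm genes with Zld-only regions (6 of 32 against a mean of 1.74: Mef2, Traf4, if, pyr, sna and stumps). Of copper response genes, 2 were nearest to Grh-only regions (Ctr1A and Hsp22), 1 to Zld-only regions (ATP7) and 0 to Twi-only regions. Hemocyte genes numbered 1 for Grh (Tl), 2 for Zld (crq and kay) and 2 for Twi (Pvr and vkg). The Twi count rose to 7 of 22 (Pvr, Pxn, Tl, crq, kay, srp and vkg) against a mean of 1.07 at a −log10 q of at least 10. With the same number of regions per list it was 5 (Pvr, Pxn, Tl, crq and vkg) against 0.822, and the permutation test called both (adjusted p = 0.0048 and 0.0288). No other setting called it. Main lists alone gave 18 genes against 15.7 (permutation test, adjusted p = 0.648) and titration lists alone 5 against 2.57 (permutation test, adjusted p = 0.762). Polycomb and Hox genes numbered 2 for each set, neuronal genes 1 for each set (Dscam1 in all 3), and germline genes 1 for Grh (stai) and 0 for Zld and Twi. Genes named in this paragraph were chosen after their counts were seen.

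**Figure D2:**
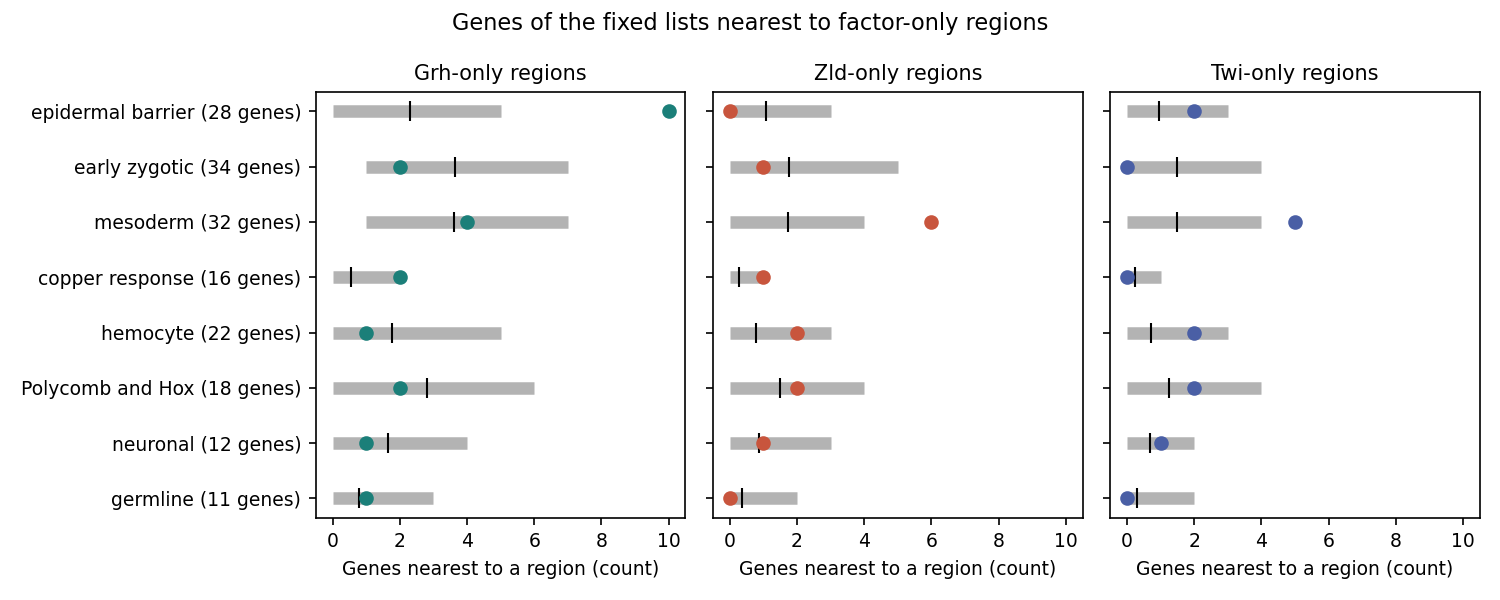
Number of genes of each fixed list nearest to at least 1 Grh-only, Zld-only or Twi-only region (points), with the mean (tick) and central 95% (grey bar) of 10000 random lists matched on territory. Epidermal barrier genes with Grh-only regions stand at 10, above a mean of 2.29.

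Only-regions lay farther from gene ends than regions of all 6 lists. Of Grh-only regions, 17.0% (14.5 to 19.7) had a summit within 500 bp of an end of a gene, against 46.4% (45.7 to 47.1) of Grh regions found in all 6 lists. The shares were 24.0% (19.7 to 28.7) against 46.6% for Zld and 14.5% (10.7 to 19.1) against 46.2% for Twi. Each difference passed Fisher's exact test over regions (adjusted p = 4.29e-67, 7.74e-19 and 2.61e-30). With main lists alone the Zld shares were closer, at 31.8% against 41.1% (exact adjusted p = 1.07e-20). The only-region shares in that setting were 16.0% for Grh and 15.3% for Twi, without the demand for a titration list. Only-regions were also weaker than regions of all 6 lists. Median fold enrichments were 1.92 against 4.40 for Grh, 2.20 against 6.4 for Zld and 1.95 against 4.37 for Twi. The sets were not matched on strength, so the lower shares cannot be assigned to factor-only regions as such. The summits of only-regions lay inside a gene for 79.1% of Grh, 75.5% of Zld and 83.1% of Twi. The gene table gives no strand here, so either end of a gene counts and promoters were not separated from 3' ends.

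Regions of 1 main list that were absent from the other main lists were then sought in the titration lists. Of 4457 such Grh regions, 19.9% (18.8 to 21.2) were in the Grh titration list, 2.54% in that of Zld and 1.66% in that of HA-Twi. Of 2624 such Zld regions, 35.8% (33.9 to 37.7) were in the Zld titration list, 21.1% in that of Grh and 23.2% in that of HA-Twi. Of 30059 such Twi regions, 1.91% (1.76 to 2.07) were in the HA-Twi titration list, 2.16% in that of Zld and 3.19% in that of Grh. In each case the own list differed from the highest other list by an exact McNemar test (adjusted p = 6.09e-183, 2.54e-44 and 2.25e-30), upwards for Grh and Zld and downwards for Twi. With the same number of regions from each list, the own list stood highest for all 3, and for Twi the share was 19.3%, against 12.3% for Zld. The comparison was chosen after the data were seen.

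**Figure D3:**
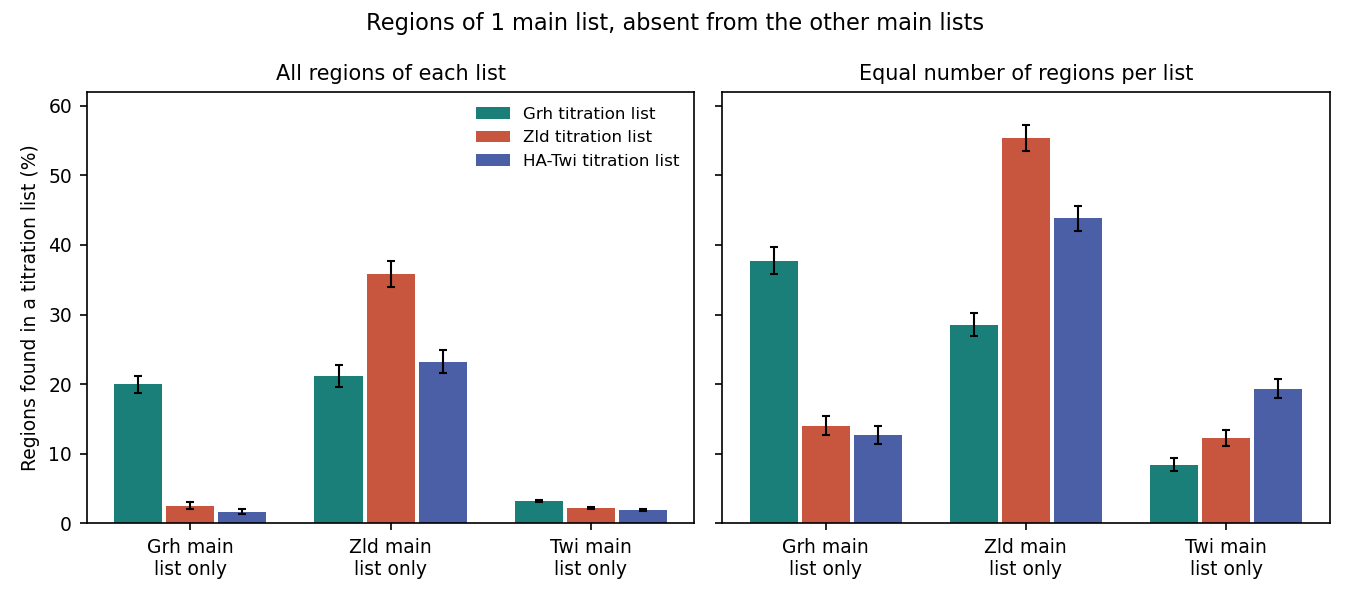
Share in percent of regions found in only 1 main list that overlap each titration list (colours), with exact binomial 95% intervals, using all regions (left) or the same number of regions per list (right). The own titration list is highest for Grh and Zld in both panels, and for Twi in the right panel only.

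Only-regions of each full-length factor were also sought in the DBD lists. The Twi list held 96.4% of the regions of the Grh DBD list and 93.8% of those of the Zld DBD list. Grh-only and Zld-only regions are absent from the Twi list by definition and Twi-only regions are in it, so the level of each share below is largely set by the definition and does not show whether a DBD alone is enough. Of the 813 Grh-only regions, 10 (1.23%, 0.591 to 2.25) overlapped the Grh DBD list and 14 (1.72%, 0.945 to 2.87) the Zld DBD list. Of the 367 Zld-only regions, 11 (3.00%, 1.51 to 5.30) overlapped the Zld DBD list and 12 (3.27%, 1.70 to 5.64) the Grh DBD list. Neither difference passed the exact McNemar test (adjusted p = 1.0 for both). Of the 296 Twi-only regions, 46 (15.5%, 11.6 to 20.2) overlapped the Grh DBD list and 33 (11.1%, 7.80 to 15.3) the Zld DBD list; the 3 sets differ by construction and were not tested against each other. With the same number of regions per list, the share in the own DBD list was 6.51% for Grh and 10.6% for Zld, and the share in the other DBD list 5.50% and 12.3%. Against the DBD titration lists the shares of Grh-only regions were 1.85% (own) and 0.738% (other), which turns the direction and does not pass after adjustment (exact adjusted p = 0.0704). In the DBD titration lists, Zld-only regions stood at 4.09% (2.31 to 6.65) for both, and Twi-only regions at 9.80% (6.66 to 13.8) for Grh and 6.08% (3.64 to 9.44) for Zld. Regions found in all 6 full-length lists were in the main DBD lists at 94.5% to 95.1%. A set of 1306 regions was in both Grh DBD lists and neither Zld DBD list, and 6 of its 10 strongest regions were nearest to grh. Since grh is the gene of the expressed domain, reads from introduced sequence were not excluded for these 6. Of this set, 713 regions were in the full-length Grh list, 597 in the full-length Zld list and 90.6% in the Twi list, the longest. The matching Zld DBD set held 2394 regions, of which 670 were in the full-length Zld list and 1348 in the full-length Grh list, and 86.9% in the Twi list. These overlaps were not tested, and the Grh list is longer than the Zld list (44658 against 33943 regions). The 4 titration libraries of the DBD carry no list in their labels, and whether they enter the DBD titration lists is not given in the sources used here.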

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

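The count of copper response genes was planned; the other tests in this part were chosen after the results were seen. The X chromosome held 35.2% (30.3 to 40.3) of the 367 Zld-only regions and 12.3% of the 1109 other only-regions, a difference between the sets by Fisher's exact test (adjusted p = 1.99e-20). The main lists differ in the same measure, with 17.5% of Zld, 11.8% of Grh and 9.7% of Twi regions on the X. With the same number of regions per list these list shares were closer, at 18.4% for Zld, 16.0% for Grh and 16.0% for Twi. The X share of Zld-only regions in that setting was 24.9% against 10.5% in the other sets. It was 22.9% against 13.3% at a −log10 q of at least 10 and 31.0% (29.2 to 32.8) against 5.23% with main lists alone. With titration lists alone, whose X shares were 17.6% for Grh, 18.3% for Zld and 18.6% for HA-Twi, it was 16.4% (15.1 to 17.8) against 15.1% in the other sets (exact adjusted p = 0.108), while the Twi share was higher than in the other sets (17.6% against 15.2%, exact adjusted p = 0.0362) and the Grh share lower (14.6% against 16.8%, exact adjusted p = 0.00855). This argues against an effect of Zld on the X as the whole cause, since the share with titration lists alone lies below the interval with main lists alone. A smaller effect of Zld on the X and a lower X share of the Grh and Twi main lists stay open, since 16.4% is slightly above the other sets with an interval that includes them.

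Of Twi regions absent from the other main lists, 1.91% were in the HA-Twi titration list, below the 3.19% in the Grh titration list, a difference in the direction opposite to Grh and Zld. The HA-Twi titration list was the shortest full-length titration list, with 25397 regions against 30394 for Grh and 27064 for Zld. It also comes from cells labelled HA-Twi, unlike the main Twi list. With the same number of regions per list the direction turned.

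Regions inside the genes of the expressed factors form a further pattern. The widest region inside zld was 2.34 times as wide as the widest other region of the Zld list (4764 against 2039 bp). The widest region inside zld was also the widest of the Zld titration list (3058 against 2034 bp). The ratio was below 1 in the other 8 lists of a factor or domain over its own gene (0.282 to 0.754). Those 8 values do not decide for or against introduced sequence. A ratio above 1 there needs a region wider than 1609 to 1995 bp, which a shorter introduced sequence could not give. The lengths of the introduced sequences were not checked here. In both Grh DBD lists the widest region inside grh (509 and 454 bp) overlaps a region held by every list. Reads from the introduced coding sequence could give wide regions inside the factor's own gene, and the widths leave this open. For grh, 3 of 5 Grh-only regions inside the gene (60.0%) were in a Grh DBD list, against 18 of the other 808 Grh-only regions (2.23%), by Fisher's exact test p = 0.000144. The share is higher inside grh, but the 5 regions lie in 1 gene and the comparison was chosen after the results were seen. It therefore does not decide whether the endogenous gene was open in the manner of other Grh-only regions. Without exons, neither reading could be checked against coding sequence, and the grh regions stay in the epidermal barrier count of 10 genes.

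Copper dose as a source of Zld-only regions was tested with the copper response genes, of which 1 (ATP7) was nearest to a Zld-only region, against a mean of 0.259 in random lists (permutation test, adjusted p = 1.0). The gene list is small, and every peak list at 500 uM and above is a Zld list. The Zld list pools wild-type and Zld cells at the same dose, so copper dose and Zld cannot be told apart from these lists.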

How the results depend on the processing

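No paired analysis was possible because each list pools libraries and no value belongs to a replicate; leaving out a replicate was not possible for the same reason. Comparisons of main-list regions with the titration lists, matching on region number, lists without the own gene and DBD lists counted as other were chosen after the data were seen. Under the alternatives, 58 values kept their direction and their side of the threshold or stayed close in size, among them the direction and call of every share near gene ends, although the Zld difference went from −22.7 to −9.25 points with main lists alone. The cause of the changes below was not tested, except where a stricter threshold or fewer lists in a definition changes a count by construction.

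At a −log10 q of at least 10 there were 313 Grh-only and 218 Zld-only regions, while Twi-only regions rose from 296 to 434. At that threshold the lists held 19816 (Grh), 32331 (Twi), 16815 (Grh DBD), 16050 (Grh DBD titration), 16543 (Zld DBD) and 16366 (Zld DBD titration) regions. Main lists alone gave 4457 Grh-only, 2624 Zld-only and 30059 Twi-only regions, and titration lists alone 6262, 3005 and 1292. For epidermal barrier genes with Grh-only regions the count was 6 at the stricter threshold, 22 with titration lists alone (permutation test, adjusted p = 0.0048 for both) and 13 with main lists alone, where the call was lost (adjusted p = 0.545). The 6 genes at the stricter threshold were Fas3, cora, grh and shg of the main setting, and Ddc and crb, which were not in it. Lac, Ubx, dpp, kkv, serp and verm dropped out. The call held at 9 of 27 genes without grh and with matching on region number (permutation test, adjusted p = 0.0144). Early zygotic genes with Zld-only regions went from below to above the mean of random lists at equal list length (5 genes), with main lists alone (12), with titration lists alone (14) and against the unmatched expectation (1 against 0.77), without passing in any of them. Mesoderm genes with Twi-only regions numbered 27 with main lists alone and 8 with titration lists alone, neither called, and the unmatched exact test called the 5 genes (adjusted p = 0.00248). Without twi the count was 4 of 31 genes and was not called (permutation test, adjusted p = 0.822).

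The own minus other DBD share of Grh-only regions, −0.492 points, became 1.92 at the stricter threshold (exact p = 0.0312, adjusted 0.0624), 1.01 at equal list length, 0.12 with 50% overlap and 1.11 with the DBD titration lists (exact p = 0.0352, adjusted 0.0704). The own minus highest other share for Twi main-list regions, −1.28 points, became 7.08 at equal list length. Motif alternatives were not run, the choice of all chromosomes and scaffolds moves nothing, and equal list length sets the number of regions per list by construction. Depth is unknown and sets no limit that can be given.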

Other observations

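The 8 families were chosen after the strongest regions had been seen, which included ZnT35C of the zinc transporters and side-IV of the immunoglobulin-domain receptors, and the zinc transporter test is counted as chosen after its result was seen. At least 3 Grh-only regions lay nearest to each of 25 genes, among them grh (5 regions, in the epidermal barrier list), melt (5), vtd (4) and, with 3 each, the ecdysone-related regulators br and Eip93F, the homeobox gene hth, the Wnt receptor gene fz2 and the focal adhesion kinase gene Fak. Of 8 such genes for Zld, CG15059, CG32639 and the transcription factor genes ct, drm and peb held 4 regions each. The 3 such genes for Twi were CG30015 and the basement membrane genes trol (perlecan) and vkg (collagen IV, in the hemocyte list), with 3 each. These genes were chosen after their values were seen, and no test was made of these counts.

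None of 24 tests of gene families passed adjustment. Of 121 cuticle protein genes, 9 were nearest to a Grh-only region (Ccp84Ac, Cpr64Ad, Cpr65Aw, Cpr66D, Cpr73D, Lcp1, Lcp65Ag2, TwdlC and TwdlT), against a mean of 3.34 in random lists (permutation test, p = 0.01, adjusted p = 0.12). The hypothesis of a cuticle theme in Grh-only regions therefore stays undecided. Of 32 chitin genes, 7 were nearest to a Grh-only region (Cda4, Cda5, Gasp, Idgf6, kkv, serp and verm), against a mean of 2.1 (permutation test, p = 0.0044, adjusted p = 0.106), and 3 of these genes are also in the epidermal barrier list. Of 8 Toll receptor genes, 4 were nearest to a Grh-only region (permutation test, adjusted p = 0.246). A zinc transporter theme in Zld-only regions rested on 1 of 15 genes, ZnT35C, against a mean of 0.263 (permutation test, adjusted p = 1.0). An immunoglobulin-domain receptor theme in Twi-only regions had 3 of 67 genes, below the mean of 4.53 but within the central 95% of random lists, 1 to 9 (permutation test, adjusted p = 1.0). The prediction made before the count named the mean as its bound, and the comparison with the range was added after the count was seen, so the theme has no positive evidence and stays undecided only by that range. Osiris, cytochrome P450 and tetraspanin genes had an adjusted p of 1.0 in the permutation test for each set.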
